A study of Homo sapiens with 6 samples.

How the data were processed

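ATAC-seq was done on human mesenchymal stem cells of 3 donors, each cultured in control medium and with PDGF-BB at 10 ng/ml for 48 h, which makes 6 samples in 2 groups. Per the labels' protocols, nuclei were treated with Tn5 transposase and the libraries were sequenced as paired-end reads. The processed data consist of 1 deposited list of regions for the whole series, with the chromosome, start and end of each region. The list names no sample, and it gives no signal, count, score, fold change or p-value, so 0 columns of values per sample were used.

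The submitters' processing notes name the genome build hg38, Trim Galore 0.4.3 (adapter trimming), Bowtie2 (alignment), Picard (a toolkit for aligned reads), MACS2 2.1.2 (peak calling) and edgeR 3.26.8 (a count model). The purposes in parentheses are what these tools generally do, since the notes name them with no role. How the regions were called (per sample or on pooled reads), how they were merged, the thresholds, the treatment of duplicates and any shift of reads for the Tn5 insertion are not given in the sources used here. These steps affect the number and width of the regions: pooling and deeper sequencing add regions, and merging the calls of several samples widens them. The deposited list holds 0 overlapping regions. No region is shorter than 200 bp, and 8993 regions (3.63%) are exactly 200 bp wide against 441 of 201 bp, so the list holds a minimum width of 200 bp. Of the regions of exactly 200 bp, 3.29% lay within 1 kb of a protein-coding gene end, against 3.71% of the 19779 regions of 201 to 249 bp (Fisher's exact test, p = 0.0808). As the list gives neither reads nor samples, the depth per sample is unknown, no replicate error can be given, and whether a region was open in control cells, in treated cells or in both cannot be read from it. Wilson 95% intervals over regions or genes cover counting error only, and the SD over the 23 chromosomes describes differences between chromosomes, not between donors.

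The coordinates were read as starts counted from 0 and ends counted from 1, because the shortest width under this reading is 200 bp, and are given here counted from 1. Genes were taken from the RefSeq gene table of GRCh38, the assembly that hg38 names. It holds 59097 genes on the chromosomes used, of which 19974 are protein-coding and 18176 are lncRNA genes. Chromosome Y and XIST were left out throughout.

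The design fixed before the data were examined used transcription start sites. The gene table used here gives the span of each gene and neither strand nor exons, so both ends of each gene were used in place of start sites, and exon and intron classes were not computed. This deviation lowers the contrast between promoters and other places, because the ends of transcription are counted too, and it misses internal start sites. A region counted as being at a gene end if it came within 1 kb of it. Other regions were placed inside protein-coding genes, inside other genes or outside genes by their midpoint. As a background, the same regions were moved by 100 kb to either side and placed again, and the shares were compared over 23 chromosomes with an exact two-sided sign test. For each gene, regions were counted in windows reaching 50 kb to either side of each end, as the mean over both ends. The planned tests of differential accessibility were not run, since they need values per sample, and the planned motif tests were not run, since they need a genome sequence.

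In all, 19 gene lists with 195 genes were fixed before the data were examined, and 195 of the 195 genes were matched by symbol. The lists held PDGF ligands and receptors, immediate-early and AP-1 genes, receptor tyrosine kinase feedback genes, contractile and SRF target genes, mesenchymal stromal surface markers, osteogenic, adipogenic and chondrogenic genes, cell cycle genes and matrix and matrix remodelling genes. They also held cytokine and chemokine genes, TGF-β and BMP response genes, growth factor genes, cholesterol synthesis genes, ubiquitous housekeeping genes and markers of haematopoietic, endothelial, epithelial and neural cells. The share of members with a region at an end was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists, at a threshold of 0.05. The median number of distal regions was set against 10000 random lists of the same size, drawn within deciles of the number of annotated gene ends within 100 kb. This percentile is a description and not a test between groups.

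Genes to be named were set by rule before the data were examined. From each list these were up to 4 members with the most base pairs covered by regions in their windows, and up to 4 members without a region within 1 kb of an end in alphabetical order. The rule also took the 10 widest regions and the 10 protein-coding genes with the most regions in their windows (12 with ties). PDGFD, SPRED1, TIMP1, POSTN, HGF, CXCL2 and PTGS2, with low values in their lists, were chosen after the values were seen. So were SPI1, CD3E, GATA1 and ITGAM, which complete the haematopoietic markers with a region at an end. Not every gene that the rule allows is named, and some are not reported here.

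The code was tested on simulated data with known answers. Counts of regions and covered base pairs in windows differed by 0 from direct counts. Of 500 random lists of 10 genes drawn from the 19974 protein-coding genes, 2.4% passed an unadjusted p of 0.05 in Fisher's exact test. Of lists of 10 genes with a true share of 40%, 82.5% passed, while 0 of 20 lists of 10 genes that all had a region did. Of random lists without an effect, 2.0% fell outside the central 95% of the random lists, with simulated counts in place of distal regions. These counts were drawn independently for each gene, whereas neighbouring genes share windows in the data. For lists with neighbouring genes, the simulation does not show how often the percentile is extreme without an effect. The analysis was run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

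Alternatives changed the distance that counts as a gene end (500 bp and 2 kb), the regions used (at least 300 bp wide, autosomes only, neighbours under 500 bp apart merged), the overlap, the genes (all annotated genes) and the windows (20 kb and 100 kb). Random lists were also drawn without matching. Settings added after the data were seen were regions of at least 1000 bp, leaving out regions of exactly 200 bp, requiring a base at the gene end itself, and random lists matched on gene length.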

Results

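Open chromatin was mapped by ATAC-seq in human bone marrow mesenchymal stem cells (MSCs), multipotent stromal cells that can form bone, fat and cartilage cells. In ATAC-seq, the transposase Tn5 inserts sequencing adapters into accessible DNA. Cells of 3 donors were cultured either in control medium or with PDGF-BB at 10 ng/ml for 48 h, which gave 3 control and 3 PDGF-BB samples. PDGF-BB is a dimer of the PDGF-B chain and a ligand of the receptor tyrosine kinases PDGFRB and PDGFRA. The design asks how accessibility differs between treated and control cells. The deposited list analysed here holds the chromosome, start and end of each accessible region for the series as a whole. It carries no value per sample, so no difference between PDGF-BB and control was drawn, and the depth of each sample is unknown. The list was instead used to describe which regions and genes lay in open chromatin in these cells.

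The list held 247774 regions on the autosomes and chromosome X, which covered 151.567 Mb of the genome (hg38 coordinates). The regions were 512 bp wide at the median, with quartiles of 321 and 805 bp and a range of 200 to 3591 bp. Among the autosomes, chromosome 17 had the most regions per Mb between its first and last region, with 96.3 per Mb, and chromosome 21 the fewest, with 69.0 per Mb. Chromosome 19 had 24.9 protein-coding genes per Mb, the highest value of the autosomes, and 89.3 regions per Mb. Its regions were also the widest of the autosomes, with a median of 560 bp.

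Most of the regions lay away from gene ends. Of all regions, 111828 (45.1%) lay inside protein-coding genes over 1 kb from any gene end, and 74696 (30.1%) lay outside annotated genes. A further 26361 regions (10.6%) lay inside other genes only, such as lncRNA genes and pseudogenes. Regions within 1 kb of an end of a protein-coding gene numbered 20042, or 8.09% (Wilson 95% interval 7.98 to 8.20%). Per chromosome this share was 8.90% ± 4.54 (SD, n = 23 chromosomes). When the same regions were moved by 100 kb, 4.02% lay within 1 kb of such an end, a ratio of 2.01. The share was higher for the listed regions than for the moved regions on 23 of 23 chromosomes (exact two-sided sign test, p = 2.38e-07). Regions near the end of another gene only made up 5.99%, against 5.29% after moving, and were also more frequent on 23 of 23 chromosomes (exact sign test, p = 2.38e-07). The share outside genes was 32.3% after moving and lower for the listed regions on 23 of 23 chromosomes. The share inside protein-coding genes was 47.1% after moving and lower for the listed regions on 21 of 23 chromosomes (exact sign test, p = 6.60e-05). The classes exclude each other and gene ends come first, so a higher share at gene ends lowers the other shares. These lower shares are therefore no separate sign of fewer regions inside or outside genes. Strand and exons were not used here, so a gene end stands for either the start or the end of transcription, and exonic and intronic regions were not told apart.

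Regions at gene ends were wider than the others. Their median width was 1027 bp against 492 bp elsewhere, with SDs over chromosomes of 56.7 and 11 bp, and they were wider on 23 of 23 chromosomes (exact two-sided sign test, p = 2.38e-07). Of the regions of 300 to 399 bp, 3.38% lay within 1 kb of a protein-coding gene end, against 3.43% after moving. This share was 16.4% among regions of 1000 to 1199 bp, 40.7% among those of 1400 to 1599 bp and 65.2% among those of 2000 bp or more. After moving, the corresponding shares were 5.02%, 6.92% and 7.62%. Wider regions thus met gene ends more often after moving too, which the sign test on widths does not allow for. The rise with width was larger for the listed regions. The 35582 regions of at least 1000 bp, which made up 14.4% of the list, held 29.1% at protein-coding gene ends.

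**Figure D1:**
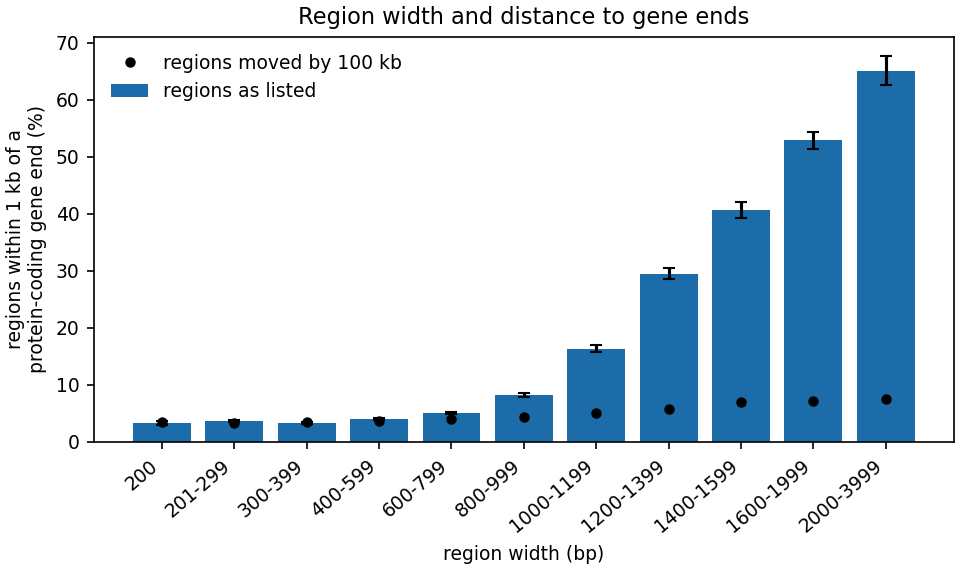
Share of accessible regions within 1 kb of a protein-coding gene end (vertical axis, percent) in classes of region width (horizontal axis, bp), with bars for the listed regions, Wilson 95% intervals as error bars and points for the same regions moved by 100 kb. The share is 3.38% at 300 to 399 bp and 65.2% from 2000 bp, while the moved regions reach 7.62%.

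The kinds of genes differed in how often a region lay at their ends. Of 19974 protein-coding genes, 16175 (80.98%, Wilson 95% interval 80.4 to 81.5%) had a region within 1 kb of an end, against 42.6% for moved regions. Regions lay at both ends of 24.4% of protein-coding genes and at neither end of 3799. The share per chromosome was 80.7% ± 6.79 (SD, n = 23). Of lncRNA genes, 56.1% had such a region, against 38.0% for moved regions. Genes of tRNAs, which are transcribed by RNA polymerase III, had such a region in 73.8% of 443 cases, against 23.1% for moved regions (higher on 20 of 21 chromosomes, exact sign test, p = 2.10e-05). For miRNA genes the share was 35.2% against 26.1%, higher on 21 of 21 chromosomes. Pseudogenes had a region at an end less often than moved regions gave, with 21.1% against 25.9% (higher on 1 of 23 chromosomes, exact sign test, p = 5.72e-06). For snoRNA genes, which often lie inside the introns of other genes, 25.1% and 24.96% for moved regions were not distinguishable (higher on 12 of 23 chromosomes, exact sign test, p = 1). A region of at least 1000 bp lay at an end of 57.9% of protein-coding genes, 24.7% of lncRNA genes and 3.62% of pseudogenes.

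**Figure D2:**
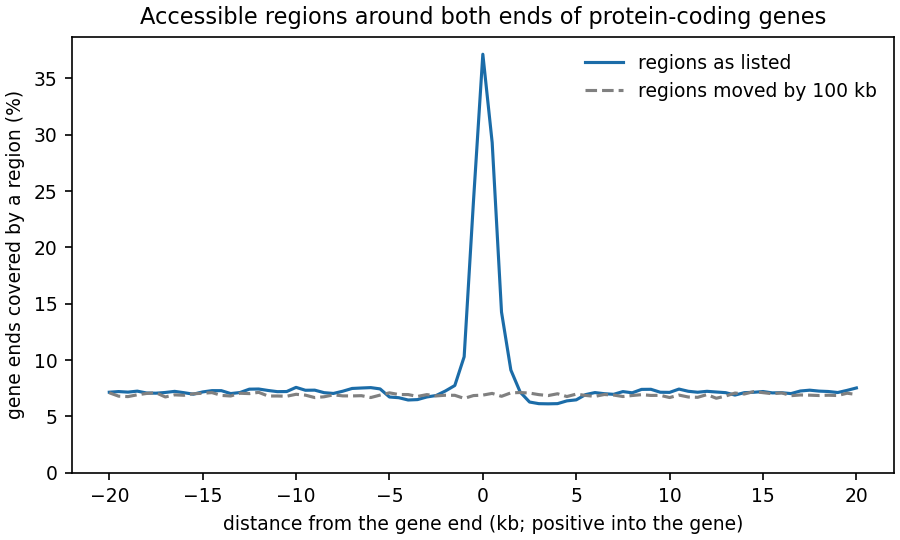
Percent of protein-coding gene ends covered by a region (vertical axis) by distance from the gene end (horizontal axis, kb, positive into the gene), for regions as listed (solid line) and moved by 100 kb (dashed line). Coverage peaks at 37.1% at the gene end itself, where the moved regions cover 6.90%.

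In each gene list, the counts of regions per window are given mainly for the members with the most base pairs covered by regions, so they lie at the upper end of their list. All 6 genes of the list of PDGF ligands and receptors had a region within 1 kb of an end. PDGFRB (chromosome 5, 150113839 to 150155845), the main receptor of PDGF-BB, had 12 regions overlapping the gene and a region at each end, the wider of 1445 bp. Counted as the mean of the 100 kb windows centred on its ends, it had 20.5 regions per window, against a median of 11.5 (quartiles 8 and 15) over all protein-coding genes. PDGFC (chromosome 4, 156760454 to 156971799), which encodes another PDGF ligand, also had 20.5 regions per window and 39 overlapping the gene. PDGFRA had 17 regions per window, and so did PDGFA, while PDGFD had 11.5, the median of all protein-coding genes. Of 15 immediate-early and AP-1 genes, many of which are induced early by growth factors, 14 had a region at an end. FOS (chromosome 14, 75278828 to 75282230) had 21.5 regions per window, JUNB had 23 and FOSL1 had 21. FOSB had a region of 1876 bp at an end and 20 regions per window. ATF3 was the exception, with its nearest region 1118 bp from an end and 9 regions overlapping the gene. All 11 feedback genes of receptor tyrosine kinase signalling, which encode phosphatases and adaptors that dampen the pathway, had a region at an end. Regions covered from 7630.5 bp of the window (SPRED1) to 16784 bp (DUSP1), with a median of 7608.5 bp over all protein-coding genes.

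**Figure D3:**
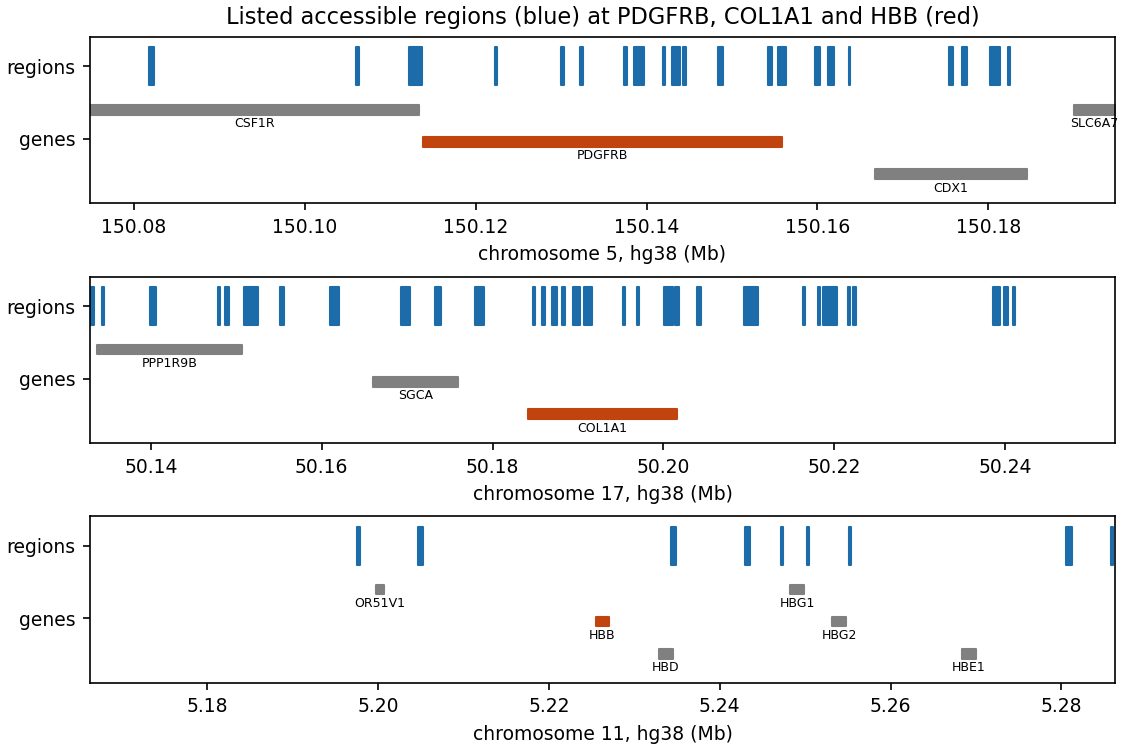
Accessible regions (blue) and genes (red for the named gene, grey for its neighbours) around PDGFRB, COL1A1 and HBB, by position on chromosomes 5, 17 and 11 (horizontal axes, Mb, hg38). PDGFRB has 12 regions overlapping the gene and COL1A1 has 10, while HBB has none and its nearest region lies 7212 bp from an end.

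All 12 matrix and matrix remodelling genes had a region at an end, among them FN1 (fibronectin, chromosome 2, 215360865 to 215436068) with 25 regions per window, the gelatinase gene MMP2 with 24.5 and COL3A1 with 23.5. COL3A1 had a region of only 373 bp at its end. TIMP1 had 10 regions per window and POSTN 11.5. Of 13 contractile and SRF target genes, 12 had a region at an end, as in TPM1 (20.5 regions per window), TAGLN (17) and TPM2 (19.5). CALD1 (chromosome 7, 134711499 to 134970729), the gene of the actin-binding protein caldesmon, had 60 regions overlapping the gene. SMTN lacked a region at an end, with the nearest at 1669 bp. All 11 TGF-β and BMP response genes had one, with 24 regions per window for the inhibitory SMAD gene SMAD7 and 21.5 for both TGFB2 and ID1. All 10 growth factor genes had one, with 24 regions per window for IGFBP5, 20 for HBEGF, 18 for FGF2 and 17 for VEGFA, but 8 for HGF. All 10 cytokine and chemokine genes had one, with 25 regions per window for CXCL1, 22 for CCL7, 21 for LIF and 19.5 for CCL2, but 9 for CXCL2 and 11 for PTGS2. CCL2 and CCL7 are neighbours on chromosome 17 and share part of their windows.

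Of 10 mesenchymal stromal surface markers, 9 had a region at an end, with 22 regions per window for NT5E (CD73), 20 for ENG (CD105) and 18.5 for CD44. THY1 (CD90) had none within 1 kb, its nearest region lying 1401 bp from an end, and 2 regions overlapped the gene. All 12 osteogenic genes had one. COL1A1 (chromosome 17, 50184101 to 50201631), which encodes the main collagen chain of bone, had 26.5 regions per window, and COL1A2 and SPARC had 20 each. Of 9 chondrogenic genes, 8 had a region at an end, with 20.5 regions per window for ACAN and a region of 1939 bp at SOX9. COL2A1, the cartilage collagen gene, had none, with its nearest region 1755 bp away. Of 11 adipogenic genes, 8 had one. PPARG (chromosome 3, 12287368 to 12434344), the main transcription factor of fat cells, had a region of 1808 bp at an end and 23 overlapping the gene. ZNF423 had 71 overlapping it, but is a longer gene (371756 bp against 146977 bp for PPARG). ADIPOQ, CD36 and KLF5 had no region within 1 kb of an end, with distances of 2042, 1797 and 3530 bp.

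Nearly all of the listed genes that most cells use were covered at an end. All 13 cell cycle genes and all 9 cholesterol synthesis genes had a region at an end, among them E2F2 with 18 regions per window, CDK2 with 13, INSIG1 with 17.5 and SREBF1 with 20. Of 10 ubiquitous housekeeping genes, 9 had one, as in ACTB (2072 bp wide) and GAPDH (1542 bp wide).

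Markers of other cell types were covered in part. Of 10 haematopoietic markers, 8 had a region at an end. The widest such region was 1272 bp at CD14, 937 bp at SPI1, 863 bp at CD34, 817 bp at CD3E and 763 bp at GATA1. It was 500 bp at ITGAM, 291 bp at PTPRC (CD45) and 200 bp at CD79A. The β-globin gene HBB had none. Of 8 endothelial markers, 5 had one, among them CDH5 with 19 regions per window, and PECAM1, TIE1 and VWF had none. Of 7 epithelial markers, 5 had one, among them CLDN4 with 18 regions per window, and CDH1 (E-cadherin) and GRHL2 had none. Of 8 neural markers, 6 had one, and NEUROD1 and OLIG2 had none. Several of the genes without a region at an end had regions inside, such as VWF with 29 and GRHL2 with 21. These are long genes, of 175794 and 188762 bp, and the counts were not corrected for length.

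No list's share of covered genes passed the test against the other protein-coding genes. By Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists, 0 lists passed 0.05, and 0 passed it before adjustment. The smallest p was 0.140, with an adjusted p of 0.476. Lists of 10 simulated genes that all had a region passed the test in 0 of 20 draws, so a list of this size could not be called higher. Restricted to regions of at least 1000 bp, a setting chosen after the data were seen, 1 list passed. A wide region lay at an end of 1 of 10 haematopoietic markers (10%), against 57.9% of the other protein-coding genes (Fisher's exact test, p = 0.00259, adjusted p = 0.0492). Genes are not independent replicates in any of these tests.

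The lists differed in how many regions away from gene ends lay around their genes, with 10 of 19 above matched random lists. Distal regions, over 1 kb from every annotated gene end, were counted in the 100 kb windows, and each list's median was set against 10000 random lists of the same size and gene density. The 11 TGF-β and BMP response genes had a median of 16.5 distal regions per window, against 8.5 for the random lists (percentile 100). The median was 15.25 for the PDGF ligands and receptors (percentile 99.9), 15 for the matrix genes (percentile 100), 14.5 for the growth factor genes (percentile 99.97) and 12 for the mesenchymal stromal surface markers (percentile 98.5). These 5 lists stayed above the central 95% of the random lists under each of 4 other settings. The receptor tyrosine kinase feedback genes (12.5), the cytokine and chemokine genes (12.75) and the contractile genes (11) also lay above it, with percentiles of 98.4, 99.7 and 98, the contractile median being equal to the upper limit and above it only by its percentile with ties shared evenly. So did the endothelial markers (12.5, percentile 98.3) and the epithelial markers (13.5, percentile 99.2). In windows reaching 20 kb from the gene ends these 5 lists fell to percentiles of 92.0, 79.8, 91.9, 87.5 and 63.5, within the central 95%. The feedback genes (percentile 97.36) and the epithelial markers (92.1) also did so in windows reaching 100 kb, and the feedback genes (96.2) and the endothelial markers (96.6) with regions of at least 300 bp. Some lists hold neighbouring genes that share part of their windows, such as KRT8 and KRT18 (epithelial) and MMP1 and MMP3 (matrix). Such members are not independent values. Of the 19 lists, 0 lay below the central 95% of the random lists. The immediate-early and AP-1 genes (median 10, percentile 95.1), osteogenic genes (10.5, percentile 93.5), chondrogenic genes (11, percentile 91.4) and cell cycle genes (10, percentile 89.9) lay within the range of the random lists. In windows reaching 100 kb from the gene ends, the immediate-early and AP-1 genes (percentile 98.5) and the osteogenic genes (percentile 97.54) lay above it, and so did the osteogenic genes with regions of at least 300 bp (percentile 99.1). The adipogenic genes (9, percentile 63.9) and haematopoietic markers (7.5, percentile 63.7) lay near the middle of the range. The adipogenic genes rose to percentile 94.6 in windows reaching 100 kb. The haematopoietic markers fell to 12.9 with regions of at least 300 bp. The housekeeping genes (6.25, percentile 20.8), cholesterol synthesis genes (6.5, percentile 18) and neural markers (5.5, percentile 6.27) lay in the lower part of the range. In windows reaching 20 kb their percentiles were 45.7, 84.4 and 33.2, so the cholesterol synthesis genes turned to the upper part.

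**Figure D4:**
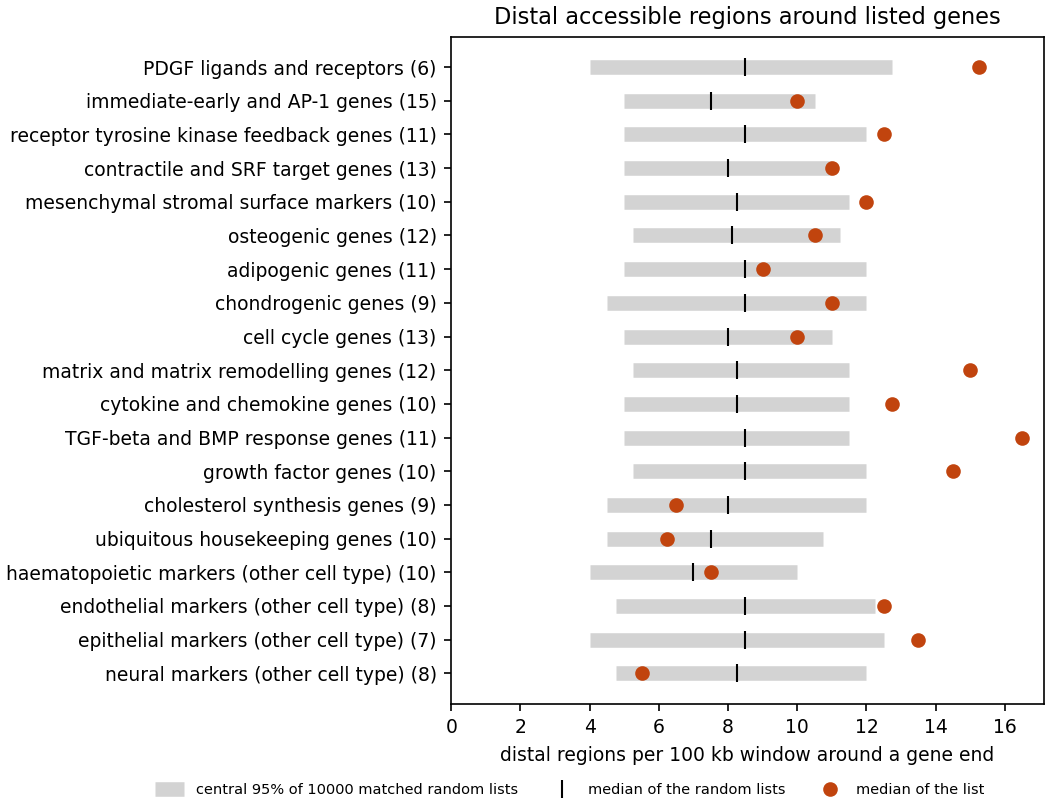
Median number of distal accessible regions in the 100 kb windows around gene ends (horizontal axis) for each of the 19 gene lists (vertical axis, number of genes in parentheses). Points give the list median, black ticks the median of 10000 random lists of the same size and gene density, and grey bars their central 95%; the TGF-β and BMP response genes lie furthest to the right, at 16.5 against 8.5.

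The HOX genes, which encode transcription factors of body-axis position, led the protein-coding genes in number of regions. HOXA4, HOXA6 and HOXA7 on chromosome 7 and HOXB1 on chromosome 17 had 33 regions per window. They were followed by HOXA5 with 32.5, HOXA3 with 31.5, HOXA9 with 31 and HOXB2 with 30.5. HOXB3, the muscle LIM protein family gene CSRP1, ARHGEF17 and the potassium channel subunit gene KCNE4 each had 29.5. Neighbouring HOX genes share most of their windows and are not independent values. At the other extreme, 570 protein-coding genes had no region in either window.

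Of the 10 widest regions, 9 lay within 90 bp of an end of a protein-coding gene. The widest of all was the exception, a region of 3591 bp on chromosome 11 (16604424 to 16608014) inside SOX6, a transcription factor gene of cartilage development, and 130463 bp from the nearest end of the gene. The next widest lay at GFRA1 (chromosome 10, 116271279 to 116274831, 3553 bp), FOXP1 (chromosome 3, 71581395 to 71584923, 3529 bp) and WSB2 (chromosome 12, 118059291 to 118062810, 3520 bp). GPSM1 (3434 bp), KLF9 (3391 bp), PLCL2 (3365 bp), HIVEP2 (3330 bp), MDGA1 (3286 bp) and THBS1 (3231 bp), which encodes the matrix protein thrombospondin, completed the 10.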

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

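Of 51 values recomputed under other settings, 30 stayed close to the reported value, 21 moved and 0 reversed. Close meant the 95% interval for a share, the quartiles for the width, 1.5 times for the ratio and for counts, and an equal count of lists at gene ends. The settings with regions of at least 1000 bp, without regions of exactly 200 bp, with a base at the gene end itself and with matching on gene length were chosen after the data were seen. The share of regions near a protein-coding gene end was 6.67% within 500 bp and 10.7% within 2 kb. It was 9.27% for regions of at least 300 bp, 7.20% when at least 50% of the region had to lie there, 14.1% with all annotated genes, 8.27% without regions of exactly 200 bp and 29.1% for regions of at least 1000 bp. Its ratio to moved regions stayed between 1.51 and 2.60, except for regions of at least 1000 bp, where it was 5.02. In these settings a longer distance or more genes take in more regions by construction, and otherwise the cause was not tested. The share of protein-coding genes with a region at an end was 76.8% within 500 bp, 85.6% within 2 kb, 78.7% for regions of at least 300 bp, 77.9% when at least 50% of the region had to lie there, 81.8% on autosomes and 57.9% for regions of at least 1000 bp. For all annotated genes it was 53.7%. The 35582 regions of at least 1000 bp had a median width of 1230 bp. Of the 19 lists, 1 passed the test of gene ends with regions of at least 1000 bp (haematopoietic markers, 3 lists before adjustment), 1 with a base at the gene end itself (haematopoietic markers, adjusted p = 0.0343, 5 lists before adjustment) and 1 left the range of random lists matched on gene length (cytokine and chemokine genes); the cause was not tested. In windows of 20 kb, 5 lists lay above the random lists in distal regions, and in the other settings 9 or 10 did, though not the identical lists. Not run were settings that need values per sample, a genome sequence or strand, namely those of the differential test, the motif tests, promoter CpG matching and outermost start sites. No paired analysis was possible because the list holds no values per sample, so the donors in both groups could not be compared. Depth is unknown, and a gene without a listed region is not shown to be closed.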

Other observations

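The gene families below and all tests here were chosen after the data were seen, except that the prediction for sparse neighbourhoods was written before its result. Genes are not independent replicates in these tests. Members of a family that lie next to each other share their surroundings, so the p-values of the families overstate the evidence.

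Of 21 gene families, 7 that are active mainly in specialised cells had few regions at their ends, while the clustered protocadherins, a mainly neuronal family, had one at 46 of 53 genes (86.8%, Fisher's exact test, adjusted p = 0.498). Of 392 olfactory receptor genes, 46 (11.7%) had a region within 1 kb of an end, against 82.4% of the other protein-coding genes (Fisher's exact test, adjusted over 21 families, p = 4.91e-198). The share was 26.6% of 94 keratin-associated protein genes, which serve hair formation (adjusted p = 2.90e-29), 15.4% of 39 beta-defensin genes (adjusted p = 7.43e-18) and 8% of 25 bitter taste receptor genes (adjusted p = 2.11e-14). It was 0 of 26 MAGE cancer-testis antigen genes (adjusted p = 1.19e-18) and 0 of 15 killer-cell immunoglobulin-like receptor genes (adjusted p = 5.28e-11). Among type I interferon alpha genes, 1 of 13 had one (adjusted p = 6.22e-08). Ribosomal protein genes had one in 96.1% of 77 cases (adjusted p = 4.62e-04) and zinc finger ZNF genes in 91.1% of 517 (adjusted p = 4.23e-10). The ZNF genes had only 6.5 regions per 100 kb window at the median, against 11.5 for random families of the same size and gene density. Collagen and integrin genes went the other way in the count per window only, with medians of 15 and 15.25 regions. These lay above the upper limits of the central 95% of random families, 12.75 and 13.5. At an end, 84.1% of 44 and 86.7% of 30 genes were covered, not distinguishable from other genes (Fisher's exact test, adjusted p = 0.821 and 0.791).

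Wide regions were less frequent at markers of other cell types pooled than at the other listed genes, but not in each list. The pooling was prompted by the haematopoietic markers. Of the 33 markers of haematopoietic, endothelial, epithelial and neural cells, 9 (27.3%, Wilson 95% interval 15.1 to 44.2%) had a region of at least 1000 bp at an end, against 112 of 162 genes (69.1%, 61.6 to 75.7%) of the other 15 lists (Fisher's exact test, p = 1.76e-05, odds ratio 0.167). Without the haematopoietic markers it was 8 of 23 (34.8%, Fisher's exact test, p = 0.00204). A wide region lay at 1 of 10 haematopoietic and 1 of 7 epithelial markers, but at 4 of 8 endothelial and 3 of 8 neural markers (Fisher's exact test against the other protein-coding genes, at 57.9%, p = 0.728 and 0.294). Of the other lists, the cholesterol synthesis genes had one in 100%, the housekeeping genes and the cytokine and chemokine genes in 90%, the adipogenic genes in 45.5% and the matrix genes in 33.3%. With regions of any width the shares were 72.7% (Wilson 95% interval 55.8 to 84.9%) and 95.1% (Fisher's exact test, p = 3.70e-04). The remaining protein-coding genes had 80.9%, between these shares and inside the markers' interval. The markers are thus not shown to differ from the remaining genes, and the contrast may come in part from the high share of the other lists. Gene length was tested as a technical explanation: random protein-coding genes of the same lengths had a wide region in 55.7% (central 95% 39.4 to 72.7%), above the 27.3% of the markers. Random genes of the same gene density had one in 58.5% (central 95% 42.4 to 75.8%), which argues against gene density as well. Without the haematopoietic markers, the 34.8% lay just below both ranges, which began at 39.1%. CpG content of the promoters stays open, since no genome sequence was used. With 33.3% for the matrix genes and 50% for the endothelial markers, wide regions are not shown to mark genes used by MSCs.

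The scarcity of regions at olfactory receptor, keratin-associated and beta-defensin genes could come from their arrangement in tandem arrays. The ZNF genes, a large family with members in arrays, had a region at an end in 91.1%. They were taken by name, and how many of them lie in arrays was not measured. The comparison therefore cannot decide on the arrangement in arrays, and it says nothing of how similar the copies are. The 525 genes of the sparse families lay in neighbourhoods with a median of 1.5 distal regions per window, against 8 for all protein-coding genes. Random protein-coding genes with as many distal regions had a region at an end in 55.4% (central 95% 51.8 to 58.7%), against 14.7% of the families. Sparse neighbourhoods therefore do not account for the whole scarcity. They may account for part of it, since 80.98% of all protein-coding genes had a region at an end. Ambiguous alignment between near-identical copies was not tested and stays open.

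The HOX clusters were picked because HOXA and HOXB genes led in regions per window, so high ranks among other genes carry little weight and the size of the gap matters. The many regions could follow from gene-dense neighbourhoods or from regions at their many gene ends. Against runs of as many neighbouring protein-coding genes of like gene density, the HOXA median was 31 regions per window (percentile 100), with a median of 13.5 and a highest value of 23 among 2141 runs. The HOXB median was 26.25 (percentile 100), against 12.5 and 23 among 3607 runs. The HOXC median was 23 (percentile 99.8), against 12.5 and 23 among 3543 runs. Gene density alone would place the clusters near these runs, and no run of like gene density reached the HOXA and HOXB medians. These clusters were picked for their high counts, and the genes of each share most of their windows. Their place above every run therefore cannot decide on gene density. The HOXC median equalled the highest run, so HOXC stays open. HOXD also stays open, with a median of 18.5 (percentile 94.4) against 12.5 and 23. For distal regions alone, HOXA had a median of 14.5 (percentile 99.7), against a median of 6 and a highest value of 15 among the runs. HOXB had 13.5 (percentile 98.5), against 6.75 and 16. Both lay above the central 95% of such runs but below the highest run. An excess over the run medians remained without regions at gene ends, so these need not be the whole explanation. How much they contribute was not tested. HOXC (11.5, percentile 93.4) and HOXD (9, percentile 79.8) lay within the central 95%, and there regions at gene ends stay open as an explanation. No biological explanation was tested, since the list does not separate the groups of the design.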
